A study of Mus musculus with 4 samples.

How the data were processed

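Expression was measured in Beta-TC-6 cells, an established mouse pancreatic beta cell line, with Affymetrix Mouse Gene 2.1 ST arrays, a single-colour platform that probes whole transcripts. The labels put 2 arrays in a group transfected with siRNA against NF90 (siNF90) and 2 in a group transfected with a negative control siRNA (siNTC). NF90 is a double-stranded RNA-binding protein. The siRNA against NF90 was a mixture of duplexes delivered with a lipid reagent, per the labels' protocols. Nothing in the labels says whether the arrays of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these arrays, which may be technical.

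The authors deposited 1 table of log2 values, with a value for each of 41345 probe sets on each of the 4 arrays. The table was made with Transcriptome Analysis Console, per the submitters' processing notes. The version, the background correction, the normalization and the summarization method are not given in the sources used here, and the values carry 2 decimals. The log base is not stated either. Base 2 was taken because between 5 and 10 values on each array exceed 11.09, the natural logarithm of the highest value that a scanner of this kind writes. Array medians were 1.68 and 1.66 in siNTC and 1.65 and 1.66 in siNF90, and the maxima lay between 11.86 and 12.01, so the arrays shared their scale. The table holds no measure of background, so a low value cannot be called detected or undetected. The number of arrays limits the precision.

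Probe sets were named from the platform annotation supplied with the table. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none here. Of those with 1 symbol, 23328 matched a gene identifier of the RefSeq table (assembly GRCm38.p6), and no symbol needed an update. No coordinates are printed, because no genome build is named for the values. Probe sets with several symbols were not named. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over the 4 arrays was used, which left 22180 genes. Ins1 and Trp53 were not analysed here, since no probe set carried their symbol alone. The depletion of NF90 is not reported here, so the siNF90 arrays are described by their label.

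The comparison was fitted before any filter with limma 3.58.1 (lmFit and eBayes without a trend, in R 4.3.3) as siNF90 minus siNTC. P-values are two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 3.92 from the shared prior. Values are given as mean ± SD over the 2 arrays of a group, and differences with the standard error of the fit. For single values an exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.33, so none was used. Of 27 gene lists fixed before the data were examined, 25 had at least 3 measured genes and were tested with limma's camera (preset inter-gene correlation 0.01, against all other genes), with adjustment over these 25 lists. With a preset correlation, camera takes its degrees of freedom from the number of genes, not of arrays. Its p-values then do not measure how far a list would vary between arrays or cultures. The list of the target and its partner held only Ilf2. The rule for mitochondrially encoded genes matched no symbol, so these genes were tested by their RefSeq names as a list added after the data were seen.

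The genes named in the text followed a rule written before the data were examined. Ilf2, Ins2, Pdx1, Mafa, Neurod1 and Cdkn1a are always given, as Ins1 and Trp53 would have been. Up to 15 genes per direction follow, in order of fold among those past the threshold, or of smallest p where none passed, with a mean in the higher group of at least the median level of 1.84. From each list up to 4 members that passed are named, or the 2 with the largest difference. Other names are said to have been chosen after their values were seen.

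The scripts were tested on simulated data made with the real gene means and a spread drawn from the fitted prior with a trend. Over 10 draws, 200 of 22180 genes were changed, all taken from genes at or above the median level. The fit without a trend recovered 44.9% of genes changed by a log2 of 1 and 96.9% of genes changed by a log2 of 2, with 1.75% false calls. With a trend it recovered 69.4% and 99.3%, with 4.52% false calls; this spread favours the fit with a trend by construction. A simulated rise of 0.3 in every gene of the p53 list was called in 10 of 10 draws. Genes were drawn independently, so this does not test the list calls under correlation between genes. Alternatives fixed before the data were examined were the replicate number as a block, a trend or a robust prior in eBayes, quantile normalization, median centring, a filter on level, the mean of a gene's probe sets, every probe set, other list tests and leaving out each array in turn. The replicate numbers are not stated to mark a shared culture or day.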

Results

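Gene expression was profiled in Beta-TC-6 cells, a mouse beta cell line that makes insulin, after transfection of siRNA against NF90 or of a control siRNA, to find genes whose expression depends on NF90. Each group had 2 arrays. Across 22180 genes, the arrays of a group correlated at r = 0.9927 (siNTC) and r = 0.9919 (siNF90), and arrays of different groups at 0.9895 to 0.9913 (Pearson, across genes, which are not independent replicates). The median absolute difference between the arrays of a group was 0.15 on the log2 scale in both groups, and the median difference between the groups was 0.02. The number of arrays limits the precision of each value.

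Ilf2, which encodes NF45, the partner of NF90, was 1.21-fold lower, at 6.44 ± 0.11 in siNTC and 6.16 ± 0.07 in siNF90 (log2, SD, n = 2 arrays each). Both siNF90 arrays lay below both siNTC arrays, and Ilf2 did not pass limma's test over all genes (adjusted p = 0.527).

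The siNF90 arrays showed higher Cdkn1a (p21, an inhibitor of cyclin-dependent kinases) and lower Slc2a2 (GLUT2, the glucose transporter of rodent beta cells), each by about a factor of 2. Cdkn1a (probe set 17335467) stood at 6.36 ± 0.04 in siNTC and 7.38 ± 0.06 in siNF90 (log2, SD, n = 2 each), a 2.02-fold difference. Slc2a2 stood at 5.9 ± 0.14 in siNTC and 4.82 ± 0.06 in siNF90, which is 2.11-fold lower. No single gene passed the test over all genes, where limma's smallest adjusted p was 0.342. At an unadjusted p under 0.05 there were 2281 genes, 1303 higher and 978 lower, where 1109 are expected with no change, and 18 higher and 20 lower genes also differed by 2-fold. A per-gene spread alone gave 24 genes at an unadjusted p under 0.05 and 2-fold, 13 higher and 11 lower. With a variance prior that follows the level of the gene, an alternative planned beforehand, 52 genes rose and 49 fell at an adjusted p under 0.05, Cdkn1a (adjusted p = 0.00633) and Slc2a2 (0.0153) among them. That count was 0 with the replicate number as a block, which leaves fewer residual degrees of freedom, so lost power alone could give it. Leaving out an array leaves a group with a single array, which cannot show whether these calls hold.

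Among the 15 named genes higher in siNF90, Syt10, a member of the synaptotagmin family of vesicle proteins, was 2.31-fold higher, at 6.02 ± 0.08 in siNTC and 7.22 ± 0.01 in siNF90. Gad2, which makes the transmitter GABA in neurons and beta cells, was 2.08-fold higher, at 5.18 ± 0.12 and 6.23 ± 0.1. Cgref1 was 2.09-fold higher and Ecel1, a membrane metalloprotease, 1.87-fold. Klb, the co-receptor of fibroblast growth factor 21, was 2-fold higher, with log2 means of 4.1 ± 0.17 and 5.1 ± 0.07. Npnt, an extracellular matrix protein, was 1.86-fold higher and Alg14, an enzyme of N-glycosylation, 1.91-fold. Snapc5, a subunit of the snRNA-activating complex, was 2.03-fold higher, from a low level of 2.54. Cd68, a lysosomal glycoprotein abundant in macrophages, was 2.18-fold higher, at 3.34 ± 0.02 and 4.46 ± 0.03. Adssl1 (2.29-fold), Glipr2 (2.01-fold), the predicted genes Gm26504 (1.89-fold) and 1700007K13Rik (2.32-fold), and the vomeronasal receptor Vmn1r24 completed this group with Cdkn1a. Vmn1r24 had a log2 difference of 1.16 from a siNTC mean of 1.02, which lies below the lower quartile of each array, so no fold is given. None passed limma's test over all genes (adjusted p from 0.342 to 0.344), and with the trend 12 of the 15 did.

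Among the 15 named genes lower in siNF90, Cntnap4, a neuronal cell adhesion protein, had the largest difference. It was 3.15-fold lower, at 3.44 ± 0.16 in siNTC and 1.79 ± 0.02 in siNF90, and the siNF90 level lies under the median of all genes. Akr1c14, a hydroxysteroid dehydrogenase, was 2.37-fold lower, and the iron exporter Slc40a1 (ferroportin) 1.95-fold lower, at 6.96 ± 0.01 and 6 ± 0.23. Brip1 and Rad51b, proteins of DNA double-strand break repair, were 1.77-fold and 2.04-fold lower. Dnm3 (dynamin) was 1.75-fold lower and Ap1s3, a subunit of a clathrin adaptor, 2.01-fold. Rgs4, a regulator of G-protein signalling, was 1.78-fold lower, and Tspan2 also 1.78-fold. Fstl5 was 2.02-fold lower, Ctnnal1 1.74-fold, Mfsd4b4 2.11-fold, the transcript 9530091C08Rik 2.57-fold and the microRNA gene Mir690 2.27-fold. None passed limma's test over all genes (adjusted p from 0.342 to 0.357), and with the trend 11 of the 15 did.

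**Figure D1:**
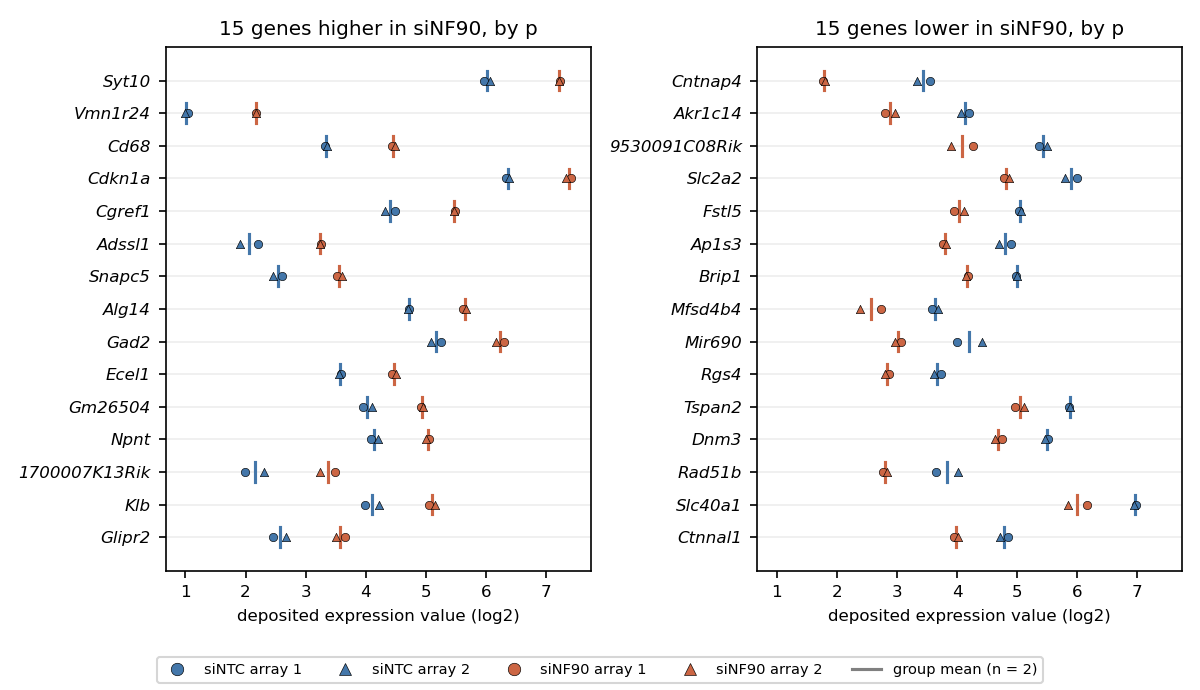
Deposited log2 expression value (horizontal axis) of the 15 genes higher (left) and the 15 lower (right) in siNF90 with the smallest p, for each of the 4 arrays (points) with the mean of each group of 2 (vertical bars). The arrays of the groups do not overlap for any of these genes, as in Cdkn1a, where siNTC lies at 6.33 and 6.39 and siNF90 at 7.42 and 7.33.

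Target genes of p53, the tumour suppressor that responds to DNA damage, rose as a list in siNF90. Of 29 measured, 23 were higher and 6 lower, and the median log2 difference was 0.23 (camera, adjusted p = 7.44e-05 over 25 lists). Adjusted p = 0.463 with an estimated correlation between genes (0.027), a setting that also leaves camera only the 2 residual degrees of freedom of the fit. Besides Cdkn1a, Zmat3, an RNA-binding zinc finger protein, stood at 4.6 ± 0.13 in siNTC and 5.54 ± 0.09 in siNF90, 1.93-fold higher. In 18 genes both siNF90 arrays lay above both siNTC arrays, and in 3 both lay below. Chance separates 2 arrays from 2 in 33.3% of genes, and 39.8% of all genes were separated. No member passed over all genes, and 5 passed adjusted over the list alone, all higher: Cdkn1a, Zmat3, Ccng1 (0.88 ± 0.15, log2 difference and SE), Trp53inp1 (0.57 ± 0.13) and Plk2 (0.51 ± 0.12). Mdm2, the ubiquitin ligase of p53, differed by 0.26 ± 0.13, and Rrm2b, a subunit of ribonucleotide reductase, by -0.44 ± 0.15. These last 5 were named after their values were seen.

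**Figure D2:**
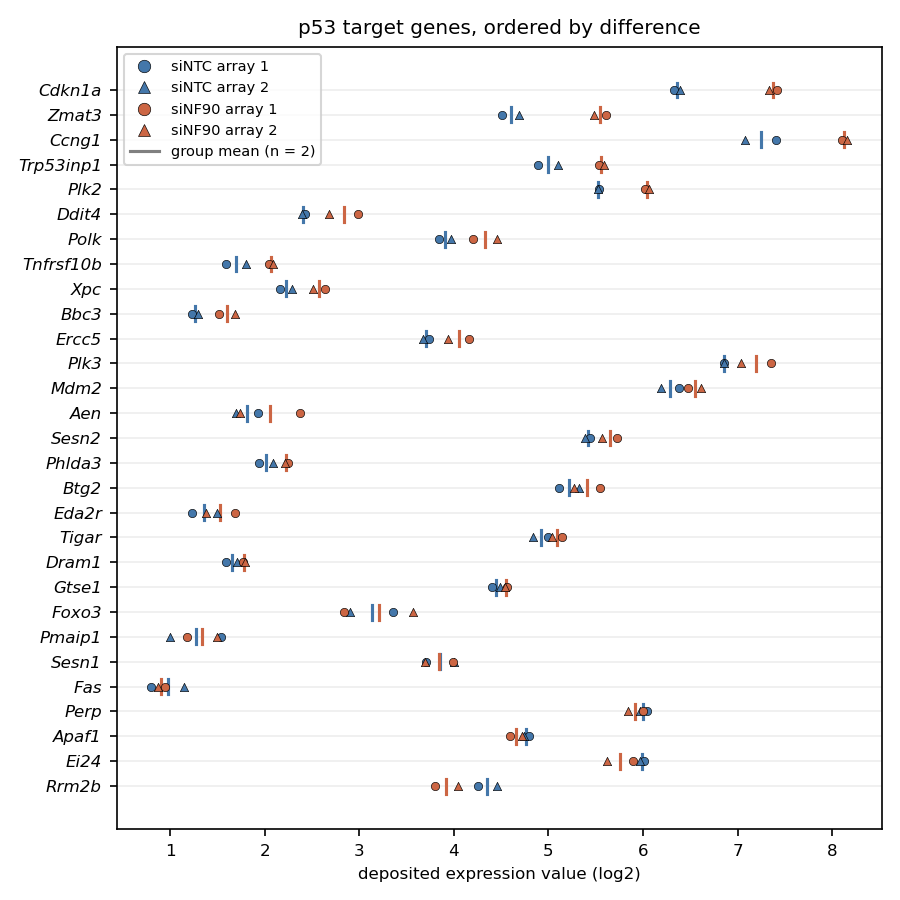
Deposited log2 expression value (horizontal axis) of the 29 measured p53 target genes, ordered by the difference between the groups, for each array (points) with group means of 2 arrays (vertical bars). The siNF90 mean is the higher one in 23 genes and the lower one in 6.

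Genes of the cell cycle fell as lists. Of 40 genes of the G1/S transition and DNA replication, 33 were lower and 7 higher, with a median log2 difference of -0.13 (camera, adjusted p = 0.000527, and adjusted p = 0.463 with an estimated correlation). Brca2, which loads the recombinase in homologous recombination, differed by -0.54 ± 0.17 (log2, SE), and Gins2, a part of the replicative helicase, by -0.51 ± 0.19. The Gins2 difference was -0.24 without the second siNF90 array and -0.78 without the first, and that of Brca2 was -0.35 without the second siNTC array. Of 42 genes of G2 and mitosis, 34 had a difference below 0 and 8 above it, with a median of -0.14 (adjusted p = 0.000527, and adjusted p = 0.463 with an estimated correlation). Nek2, a centrosomal kinase, differed by -0.56 ± 0.13 and Ect2, an exchange factor of cytokinesis, by -0.46 ± 0.12. With the trend only Ect2 of these cell cycle genes fell (adjusted p = 0.0222), and no member of either list passed over all genes or adjusted over the list alone in the planned test. The proliferation marker Mki67, named after its value was seen, differed by -0.05 ± 0.12.

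Ribosomal protein genes rose as a list, with 49 of 67 higher and a median log2 difference of 0.13 (camera, adjusted p = 0.00214, and adjusted p = 0.606 with an estimated correlation). The members with the largest differences went both ways, Rps7 by 0.72 ± 0.15 (from a low level of 1.84) and Rps13 by -0.59 ± 0.22. Genes of glycolysis and of the response to low oxygen also rose as a list, with 21 of 27 higher and a median of 0.12 (adjusted p = 0.0101, and adjusted p = 0.463 with an estimated correlation). Bnip3, a mitophagy receptor induced by hypoxia, differed by 0.57 ± 0.12, and the glucose transporter Slc2a1 by 0.43 ± 0.12. No member of either list passed over all genes or adjusted over the list alone, while with the trend 3 ribosomal protein genes rose, Rplp1 (adjusted p = 0.0227), Rpl41 (0.034) and Rpl32 (0.0389), named after their values were seen. Without the first siNF90 array neither list passed (adjusted p = 0.1 for ribosomal proteins and 0.11 for glycolysis and hypoxia), and without the first siNTC array the glycolysis list did not (0.103).

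**Figure D3:**
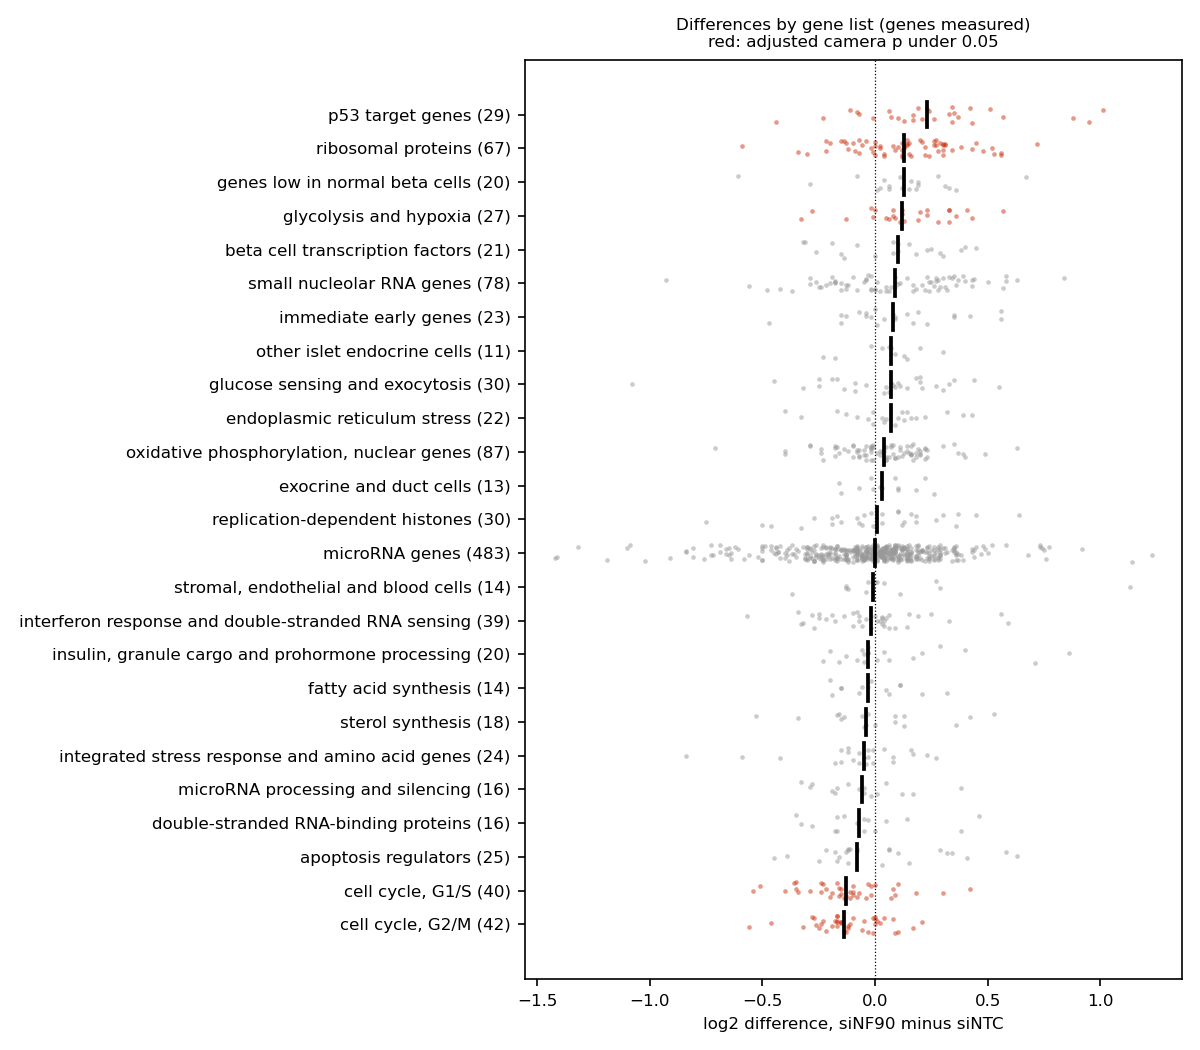
Log2 difference, siNF90 minus siNTC (horizontal axis), of each measured gene (points) in the 25 gene lists, with the list median as a black bar and the number of genes in parentheses. Lists past the threshold are red; the p53 target genes have the highest median, 0.23, and the G2/M genes the lowest, -0.14.

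Genes that define beta cells did not shift as lists. Transcription factors of the beta cell had 13 of 21 members higher (median 0.1, adjusted p = 0.391). Pdx1, which activates the insulin gene, differed by 0.08 ± 0.13, Neurod1 by 0.18 ± 0.13, Mafa by 0.38 ± 0.15, Nkx6-1 by 0.45 ± 0.12 and Hnf4a by 0.4 ± 0.14. For Pdx1 the groups overlapped, while both siNF90 arrays lay above both siNTC arrays for the other 4. Insulin, granule cargo and prohormone processing had 9 of 20 members higher, with a median of -0.03 but a mean of 0.09 and an upward direction in the test (adjusted p = 0.624). Ins2, an insulin gene, was at 7.99 ± 0.01 in siNTC and 7.94 ± 0.09 in siNF90, a difference within the spread between arrays. Nptx2, a secreted pentraxin, was 1.81-fold higher and the granule protein Vgf 1.64-fold higher, and these 2 passed adjusted over the list alone, while none passed over all genes. With the trend Nptx2 and Ptprn, a granule membrane protein named after its value was seen, rose (adjusted p = 0.0389 and 0.0405). Glucose sensing and exocytosis had 19 of 30 higher (median 0.07, adjusted p = 0.783). Slc2a2 was the member that passed adjusted over the list alone, and Rab3d, a granule GTPase, differed by 0.55 ± 0.14. Genes kept low in normal beta cells had 17 of 20 higher (median 0.13, adjusted p = 0.166), with 2 past the threshold adjusted over the list alone. These were Acot7 at 0.67 ± 0.14 and Cxcl12 at -0.61 ± 0.12.

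Genes used as markers of other cell types did not shift as lists. Gcg (glucagon), named after its value was seen, stood at 8.62 in siNTC, so these genes need not mark other cells in this line. For the other islet endocrine cells, 8 of 11 markers were higher (median 0.07, adjusted p = 0.696), with Irx2 at 0.3 ± 0.15 and Sst (somatostatin) at -0.23 ± 0.13. Exocrine and duct markers had a median of 0.03 over 13 genes (adjusted p = 0.801), with Bhlha15 at 0.26 ± 0.14 and Krt7 at 0.1 ± 0.13. Only these 2 of the 13 lay at or above the median level in either group. Stromal, endothelial and blood markers had a median of -0.01 over 14 genes, with a mean of 0.07 and an upward direction in the test (adjusted p = 0.801), and a median of 0.01 with arrays centred on their medians. Only Cd68 of these 14 lay at or above the median level in either group, and it passed adjusted over the list alone. The 10 mitochondrially encoded genes, an added list, had a median of -0.06 (camera, adjusted p = 0.131 as the only list of its family), and in ND6 the first siNTC array stood apart, at 8.27 against 6.76 on the second. COX3 differed by -0.16 ± 0.13.

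Genes of RNA biology, in which NF90 acts, did not pass as lists in camera, which asks for a directional shift. Limma's fry, asked for change in either direction, gave unadjusted p = 0.000134 for double-stranded RNA-binding proteins and 0.000239 for small nucleolar RNA genes. That test does not compare a list with other genes. It gave 0.000561 for nuclear genes of oxidative phosphorylation, so a small value is not particular to RNA biology. Double-stranded RNA-binding proteins had 12 of 16 members lower (median -0.07, adjusted p = 0.253), with the RNA-editing enzymes Adar at 0.46 ± 0.14 and Adarb1 at 0.38 ± 0.18. Adarb1 lay at 4.2 and 4.68 on the siNF90 arrays against a siNTC mean of 4.06, so most of its difference came from the second array. MicroRNA processing and silencing had 11 of 16 lower (median -0.06, adjusted p = 0.253), with Tnrc6c at 0.38 ± 0.13 and the helicase Ddx5 at -0.33 ± 0.12. The 483 microRNA genes were taken by symbol, which includes a few host genes such as Mir100hg and Mir99ahg. They had a median of 0 (adjusted p = 0.315), and 150 of them lay at or above the median level in either group. Mirlet7f-1 differed by -1.42 ± 0.23 and Mir186 by -1.41 ± 0.36, without passing over all genes. Mirlet7f-1 lay at 1.33 on both siNF90 arrays, below the array medians and without a measure of background, and its neighbours Mirlet7d and Mirlet7a-1 differed by 0.23 ± 0.28 and 0.19 ± 0.29. Small nucleolar RNA genes had 46 of 78 higher (median 0.09, adjusted p = 0.196), with Snord53 at 0.84 ± 0.15 and Snord23 at -0.93 ± 0.19. The interferon response, which double-stranded RNA can start, had 19 of 39 members higher (median -0.02, adjusted p = 0.391), with Ifi35 at 0.59 ± 0.14 and Herc6 at -0.57 ± 0.15. Only 18 of these 39 lay at or above the median level in either group. Replication-dependent histones were split evenly over 30 genes (median 0.01, adjusted p = 0.942), with H2ac1 at -0.75 ± 0.35 and H2ac21 at 0.64 ± 0.25. Only 17 of these 30 lay at or above the median level in either group. The H2ac1 difference was -0.2 without the second siNF90 array and -1.31 without the first. In none of these lists did a member pass over all genes or adjusted over the list alone. With the trend Snora33, named after its value was seen, rose from 9.31 to 9.59 (adjusted p = 0.0465), and Mir690 fell (0.0389).

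The remaining stress and metabolic lists did not pass either, and none of their members did over all genes or adjusted over the list alone. Endoplasmic reticulum stress had 14 of 22 genes higher (median 0.07, adjusted p = 0.511), with Sdf2l1 at 0.43 ± 0.12 and Edem1 at -0.4 ± 0.12. The integrated stress response had 17 of 24 lower (median -0.05, adjusted p = 0.253), with Trib3 at -0.84 ± 0.19 and Cth at -0.59 ± 0.24. Immediate early genes had 14 of 23 higher (median 0.08, adjusted p = 0.312), with Nr4a2 and Jund both at 0.56 (SE 0.17 and 0.16). Apoptosis regulators had 11 of 25 higher (adjusted p = 0.942), with a median of -0.08 but a mean of 0.02, downward in camera and upward in fry. Bid differed by 0.63 ± 0.21 and Bak1 by 0.58 ± 0.17. Sterol synthesis had a median of -0.04 over 18 genes (adjusted p = 0.783), with Insig1, a sensor of sterol levels, at -0.53 ± 0.12 and Mvd at 0.53 ± 0.21. With the trend Insig1 fell (adjusted p = 0.0153). Fatty acid synthesis had a median of -0.03 over 14 genes (adjusted p = 0.801), with Srebf1 at 0.32 ± 0.12 and Me1 at 0.21 ± 0.12. Nuclear genes of oxidative phosphorylation had 50 of 87 higher (median 0.04, adjusted p = 0.624), with Cox7a2l at 0.63 ± 0.15 and Ndufaf5 at -0.71 ± 0.15.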

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

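The limits of fold and p for probe sets without a single gene name were chosen after seeing the data. Outside the genes tested, 17824 probe sets carry no gene symbol here or several. Among them, 10 were at least 2-fold higher and 32 at least 2-fold lower in siNF90 at an unadjusted p under 0.001, and none passed limma's test over all probe sets (smallest adjusted p = 0.457). The probe sets 17206023 and 17208089 are given because they had the smallest p among the higher ones and lie outside the genes that the report's comparison tested. Probe set 17206023 had a log2 difference of 2.02, with means of 1.3 in siNTC and 3.32 in siNF90. Probe set 17208089 had a difference of 1.58, with means of 1.64 and 3.21. Of the lower ones, the smallest p belonged to 17420432, with a difference of -1.68 (means of 5.42 and 3.74), and to 17207053, with -1.82 (means of 3.08 and 1.26). The lower mean of 17206023, 17208089 and 17207053 lies below every array's median, and there is no measure of background for it here. None of the 4 has a gene name in the annotation used here.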

How the results depend on the processing

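The tests with a trend and an array left out, or with a trend and a block, were chosen after seeing the data. No gene passed in the planned fit, nor under a robust prior, quantile normalization, median centring, the filter on level, the mean of a gene's probe sets or every probe set (smallest adjusted p from 0.19 to 0.457). With a trend in the prior, 101 genes passed, 17 of them by at least 2-fold, but 0 did with the trend and the block (smallest adjusted p = 0.444). The block leaves fewer residual degrees of freedom, so lost power alone could give this. Leaving out an array, with or without the trend, leaves a group with a single array, which cannot show whether gene calls hold. The count at an unadjusted p under 0.05 was 2281 (2715 with the trend), and a per-gene spread without a shared prior gave 24 genes at an unadjusted p under 0.05 and 2-fold. The fit with the replicate block called 0 genes (smallest adjusted p = 0.591) and 5 lists, the p53, G1/S, G2/M, ribosomal, and glycolysis and hypoxia lists that also passed without it (adjusted p from 0.000335 to 0.00999), so without the trend it changed no call. Arrays of the same number did not deviate together (correlation -0.02 across genes), which does not settle whether the numbers mark a shared culture or day. Of the lists, 5 passed under camera on ranks, the trend, the filter, both scalings and the mean of probe sets. None, 0, passed with an estimated correlation (smallest adjusted p = 0.463) or with directional fry (0.111). That form of fry asks whether a list's genes move one way on balance, and does not compare them with other genes. The estimated correlation also leaves camera only the 2 residual degrees of freedom of the fit, so its p-values reflect that loss as well. Leaving out each array gave 3 to 6 lists. The p53 and both cell cycle lists passed each time, and genes low in normal beta cells passed only without the second siNTC array (adjusted p = 0.0416). Without an array, the lone sample of its group is assumed to vary like the other group. Small differences changed sign without 1 siNF90 array, in Ins2 (from -0.11 to 0.02, positive without the first), Pdx1 (from -0.03 to 0.17, negative without the second) and Krt7 (from -0.02 to 0.21, negative without the second). The causes were not tested. Among the named genes with larger differences, those of H2ac1, H2ac21, Bid, Rps13, Mvd, Brca2, Gins2, Cth and ND6, none of which passed, moved by over 1.5 times without 1 array (ND6 from -1.86 to -0.35). Smaller differences also moved by over 1.5 times, among them those of Adarb1, Mafa, Neurod1, Irx2 and Sst. Both scalings left the median difference of all genes at 0.02 to 0.03.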

Other observations

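The tests of other splits of the arrays and of microRNA genes without their large clusters were chosen after the results were seen, as were the genes named in this part outside the gene lists. With the trend in the variance prior, which gave 101 genes, Maged1, a member of the melanoma antigen family, rose from 8.08 to 8.87 on the log2 scale (adjusted p = 0.0153). The integrin subunit Itgav rose from 6.08 to 6.82 and the prolyl isomerase Fkbp11 from 6.4 to 7.17 (0.0153 for both). The synaptic vesicle protein genes Sv2b and Sv2c were higher by 0.61 and 0.84 (0.0222 and 0.0361). The mitochondrial chaperone Hspa9 was 1.39-fold lower and the mitochondrial peroxiredoxin Prdx3 1.64-fold lower (0.0153 for both). Prkaa1, a catalytic subunit of AMP-activated protein kinase, was 1.52-fold lower (0.0153), and the transferrin receptor gene Tfrc 1.33-fold lower (0.0426). None of these passed in the planned fit, and no gene passed with the trend and the replicate block, which leaves fewer residual degrees of freedom.

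The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split shifted 5 lists and the highest of the others 0, so 1 split of the 3 reached the real value. The other splits hold any difference between siNF90 and siNTC in their residual spread. They gave 726 and 802 genes at an unadjusted p under 0.05 (limma), where 1109 are expected with no change. They therefore do not show what no change would give.

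Target genes of p53 were higher in siNF90. A shift that follows the level of a gene is argued against, since the list median of 0.23 lay at percentile 100 of 10000 random lists matched on level, whose central range was -0.07 to 0.11. A few strongly changed genes do not carry the list alone, since the 24 genes left without the 5 that pass over the list alone still shifted up (median 0.18, camera, adjusted p = 0.00513 as the only test of its family, at the preset correlation). The whole list did not pass with an estimated correlation (adjusted p = 0.463). The depletion of NF90 and an effect of the siRNA duplexes on other transcripts stay open and were not tested.

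Genes of the cell cycle were lower in siNF90. A shift that follows the level of a gene is argued against by percentiles of 0.02 for the G1/S genes (random lists -0.07 to 0.08) and 0.01 for the G2/M genes (random lists -0.06 to 0.07). No single array carries the shift, since the highest camera p without each array in turn was 0.00349 for G1/S and 0.00128 for G2/M, at the preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.463 for both). The estimates were -0.0236 for G1/S and 0.0116 for G2/M, below or near the preset 0.01. That setting also leaves camera only the 2 residual degrees of freedom, so the loss cannot be read as correlation alone. Mki67 differed by -0.05 ± 0.12 and the replication-dependent histones had a median of 0.01. Only 17 of the 30 histone genes lay at or above the median level in either group, so their median says little. No biological explanation was tested.

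Ribosomal protein genes were higher in siNF90. The list median of 0.13 lay at percentile 100 of random lists matched on level (-0.05 to 0.06). It lay at percentile 99.82 of lists matched on level and genomic span (-0.02 to 0.1). This argues against a shift set wholly by level or by level and span. The range matched on span lay higher than that matched on level alone, so span may account for a part of the shift. These random lists treat genes as independent, and with an estimated correlation the list did not pass (adjusted p = 0.606). Differences in RNA quality between arrays may contribute and were not tested. The p53 and cell cycle lists were matched on level only, so genomic span was not tested for them.

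Among 483 microRNA genes, a few host genes included, 42 were lower and 18 higher in siNF90 at an unadjusted p under 0.05. Of these, 25 lower and 10 higher genes had a mean over the 4 arrays at or above the median level. The rest lay below it. The other splits of the arrays gave 18 lower and 14 higher, and 15 and 11. Those splits hold any difference between the groups in their residual spread, which tends to lower their counts, so they are no measure of chance. Of the small nucleolar RNA genes, 3 were lower and 10 higher, against 0 and 0, and 1 and 1, in the other splits. That list did not pass camera (adjusted p = 0.196), was not set against matched random lists, and was not compared with the microRNA genes. The hypothesis that microRNA genes are lower beyond the noise of such probe sets was tested against random lists matched on level and spread. The excess of 24 lay at percentile 100 (random lists -18 to 6). Without clusters of 10 or more neighbouring genes, 31 of 404 were lower and 9 higher, an excess of 22, again at percentile 100 (random lists -15 to 6), so the large clusters alone do not carry it. Of the 4 large clusters, whose differences were not tested, those from Mir743 to Mir465 (14 genes, median 0.01) and from Mir673 to Mir370 (10 genes, median 0.12) had 0 genes higher, with 0 and 1 lower. Of 33 genes from Mir882 to Mir409 on chromosome 12, 9 were higher and 1 lower (median 0.14), and of 22 from Mir669e to Mir669h on chromosome 2, 9 were lower and 0 higher (median -0.28). Neighbouring microRNA genes are not independent, and the list did not shift in camera (adjusted p = 0.315). The excess may reflect precursor levels in the siNF90 cells, since the probe sets do not separate precursor from mature microRNA, and this was not tested.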
